A study of Mus musculus with 16 samples.

How the data were processed

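RNA of mouse lymph node B cells was measured in 16 libraries, in 4 groups of 4, all from day 7 after immunization with NP-KLH, a hapten coupled to a carrier protein. The labels name dark zone (DZ) and light zone (LZ) cells, the 2 compartments of the germinal centre, and for each a sorted sample (sort) and an immunoprecipitated one (sort-IP, here IP). RiboTag mice carry an epitope tag on the ribosomal protein Rpl22, so that an antibody to the tag pulls down ribosomes with the messenger RNA bound to them. The labels name the RiboTag design and the IP but do not say what was precipitated, and no IP from untagged cells was analysed here. Poly(A) RNA was isolated on oligo(dT) beads and made into libraries with a bulk form of MARS-seq, a 3' end protocol, per the labels' protocols. Groups and replicate numbers were taken from the sample titles. Nothing in the labels says that the replicates are separate animals. Xist and Y-linked counts, given below, part each group into 2 male and 2 female libraries, so at least 2 animals stand behind each. Within a sex the replicates may be technical, so p-values measure the spread between these samples, which may be partly technical.

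The authors deposited 1 table per zone, with raw counts per gene for its 8 libraries, per the file headers. Trimming, alignment and counting tools named in the submitters' processing notes are cutadapt, STAR and HTSeq, without versions or roles, with the mm10 genome. Whether molecular identifiers were collapsed and whether counting used strand are not given in the sources used here. The deposited tables also hold the authors' log2 fold change of sorted cells over IP, and their p-value and adjusted p-value, whose adjustment matched a Benjamini-Hochberg (BH) adjustment over the rows of the table. A column of the authors marks genes as passing. A further 16 columns per table, 32 in all, were not used here. Genes number 9663 for the DZ and 9463 for the LZ, of which 9245 are in both. The smallest row maximum was 6 counts in each table, so genes below that in all 8 libraries of a zone were not analysed here. Comparisons between zones were made on the shared genes. Neither table has a row for genes of the mitochondrial genome or immunoglobulin genes, and these, like Prdm1, were not analysed here.

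Each pair of groups was compared on its own 8 libraries with edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3), after edgeR's filter on low counts and TMM scaling, with BH adjustment and a threshold of 0.05 on the adjusted p. The test of whether the IP effect differed between zones (the interaction) used all 16 libraries. Adjusted p-values of genes are from this test unless another is named. Levels are CPM, counts scaled to a common total, on TMM-scaled library sizes over all 16 libraries, given as mean ± SD, and log2 fold changes are given ± standard error (SE). Gene lists were tested with camera (limma 3.58.1) with the inter-gene correlation preset at 0.01 and BH adjustment over the lists of a comparison, and again with a correlation estimated per list. For each list, genes past the threshold were counted over all genes tested and adjusted over the list alone. Shares of counts were compared with exact two-sided permutation tests over the 70 arrangements of 4 against 4, which cannot give a p below 0.0286. Locations are 1-based on GRCm38 (mm10) from the GENCODE M21 annotation, matched by symbol for 7940 of 8236 tested genes. M21 need not be the annotation the authors counted with.

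The lists were dark zone, light zone, mitosis, DNA replication, germinal centre identity, antibody-secreting cell, resting B cell, ribosomal protein, translation factor (with other transcripts that begin with a terminal oligopyrimidine tract), snoRNA host, nuclear noncoding RNA, nuclear-encoded respiratory chain, histone, endoplasmic reticulum, chromatin remodeler, immediate early, MYC and anabolic, apoptosis and short-lived regulator genes. Lists of other cell types were T cell, natural killer, myeloid, stromal and erythroid markers. The genes named follow a rule. Smarca5, the subject of the series title, and Rpl22 come first. Next come the 10 largest rises and the 10 largest falls past the threshold with a mean of at least 5 CPM and no overlap between the groups, leaving out predicted and clone-named genes. From each list come up to 4 members past the threshold, by adjusted p, and up to 3 not past it, by expression, of which the text gives examples. Cxcr4, Foxo1, Cd83, Cd86, Myc, Bcl6, Ccnb1 and Irf4 are given whatever their result, and 1 other gene of this part of the rule is not reported here. The groups, comparisons, lists, naming rule and alternatives were fixed before the data were examined, apart from the alternatives named below as added.

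Total counts ran from 1417199 to 3438965 in the DZ sort libraries, 1447952 to 2961587 in DZ IP, 1912878 to 2569141 in LZ sort and 993379 to 1779371 in LZ IP. No 2 libraries of a group agreed within counting error (lowest chi-square per degree of freedom 3.24), so each counted as 1 replicate. Counting intervals and floors cover counting error only. The tests were tried on simulated counts with 100 genes changed 2-fold and 100 changed 4-fold. At 2-fold the test recovered 50% of changed genes in DZ IP against sort (7757 genes), 64% in LZ IP against sort (7619), 50% in DZ against LZ sort (7634), 74% in DZ against LZ IP (7350) and 24% for the interaction (8217). At 4-fold it recovered 89%, 91%, 89%, 92% and 89%, with 12, 5, 12, 11 and 4 false calls. On the 7634 genes of DZ against LZ sort, camera gave p = 1.22e-92 for a raised set and 0 of 20 random sets under 0.05, and the GC correction took a simulated tilt from a correlation of 0.85 to 0.05. The simulated genes were drawn independently, so the random sets do not show how camera behaves on correlated genes.

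The replicate numbers are shared by all groups. Deviations from the group means over 3194 genes correlated between same-numbered DZ sort and LZ sort libraries at 0.71, 0.64, 0.52 and 0.77. The highest correlations of these DZ libraries with an LZ library of another number were 0.63, 0.61, 0.43 and 0.21, so margins were small for numbers 1 to 3. Each library correlated best with its own number. In both groups numbers 1 and 2 lack Xist counts and 3 and 4 hold them, which also raises these correlations. Each library thus had only 1 library of another number with like Xist status to compete with. That the numbers pair these sorted samples was therefore taken as an assumption, which these correlations do not settle. The other comparisons are not paired by number. Alternatives were the replicate number as a block, DESeq2 size factors, DESeq2 1.42.0 as the tool, no filter, a filter of 10 counts in 4 libraries, a fold of at least 2, all 16 libraries in one fit, each library left out in turn, and genes of at least 50 CPM for the correlation between zones. Added after the data were seen were the presence of Xist counts as a block, fits within the libraries with and without Xist counts, thinning to the smallest library, a correction for GC content (of the last 1000 nt of transcripts), summing symbols that differ only in letter case, and, for the correlation between zones, sorted libraries of different numbers in each zone and regroupings of the libraries.

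Such pairs of symbols number 30 in the DZ table and 22 in the LZ table, for example TMSB4X and Tmsb4x, and the split of counts between them is uncertain. With strand not stated, counts of an antisense transcript such as Toporsos cannot be told from those of its partner. Ribosomal protein genes have many processed pseudogenes, and their counts are uncertain where reads were shared. Histone messages mostly lack a poly(A) tail, so a poly(A) library holds few of them.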

Results

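Germinal centre B cells of RiboTag mice were profiled 7 days after immunization, as RNA of the sorted dark zone (DZ) and light zone (LZ) cells and as the RNA of an immunoprecipitation (IP) from each. The design gives 4 comparisons, IP against sorted cells in each zone and DZ against LZ in each kind of RNA, and the test of whether the IP effect differed between the zones. Each group held 4 libraries, with 993379 to 3438965 counts and 9212 to 9613 genes with counts per library. The libraries also differed within groups. Xist, the noncoding RNA of the inactive X chromosome (chromosome X, 103460366 to 103483254), had counts in replicates 3 and 4 of the DZ sort, LZ sort and DZ IP groups and in replicates 1 and 2 of LZ IP. The libraries without Xist counts held counts of the Y-linked genes Ddx3y, Eif2s3y and Kdm5d. Those with Xist counts held 0 of them, apart from 1 count of Ddx3y in LZ sort replicate 4. In the sorted cells, ribosomal protein genes took 23.1 to 26.8% of counts in the libraries without Xist and 12.6 to 15.5% in those with it, against 19.3 to 22.9% in all IP libraries. Values within the libraries with and without Xist counts, 2 against 2, therefore stand beside the counts of genes, the correlations and the lists that passed, apart from the interaction, which was not fitted within them. The same libraries gave the calls, so a called gene that keeps its direction in such a part is no independent support.

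Smarca5, which encodes the ISWI chromatin remodeler named in the series title (chromosome 8, 80698507 to 80739497), was scarce in sorted cells and higher in the IP. It stood at 19.5 ± 7.85 CPM in DZ IP against 0.739 ± 1.12 in DZ sort (SD, n = 4), a log2 fold change of 4.12 ± 0.60 (edgeR, adjusted p = 0.00328). The 4 DZ sort libraries held 0, 0, 9 and 1 counts of it and the DZ IP libraries 34 to 44. In the LZ it stood at 25.2 ± 4.13 against 4.53 ± 5.19 CPM (2.46 ± 0.56, adjusted p = 0.0274), from 1 to 28 counts in the sorted libraries and 18 to 48 in the IP. The DZ call held with each library left out. The LZ call was lost without LZ sort replicate 2 (adjusted p = 0.0748) or LZ IP replicates 1 (0.0652), 3 (0.0750) or 4 (0.0767). Within the libraries with Xist counts Smarca5 was higher in the IP by 3.25 in the DZ (adjusted p = 0.0209) and by 1.80 in the LZ (0.364). Without Xist counts it was higher by 3.84 in the LZ (2.69e-08), and in the DZ both sorted libraries were at 0 counts. Between the zones, Smarca5 in the IP gave −0.44 ± 0.27 (adjusted p = 0.451), and too few counts were left to test it in the sorted cells. Rpl22 (chromosome 4, 152325742 to 152334071), the gene that carries the tag in RiboTag mice, did not pass in any comparison. Its levels were 45.0 ± 3.16 CPM in DZ IP, 36.7 ± 6.57 in DZ sort, 57.4 ± 14.1 in LZ IP and 51.2 ± 3.92 in LZ sort, with adjusted p-values of 0.288, 0.624, 0.197 and 0.37 for the IP in the DZ and LZ and for the zones in sorted cells and IP.

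**Figure D1:**
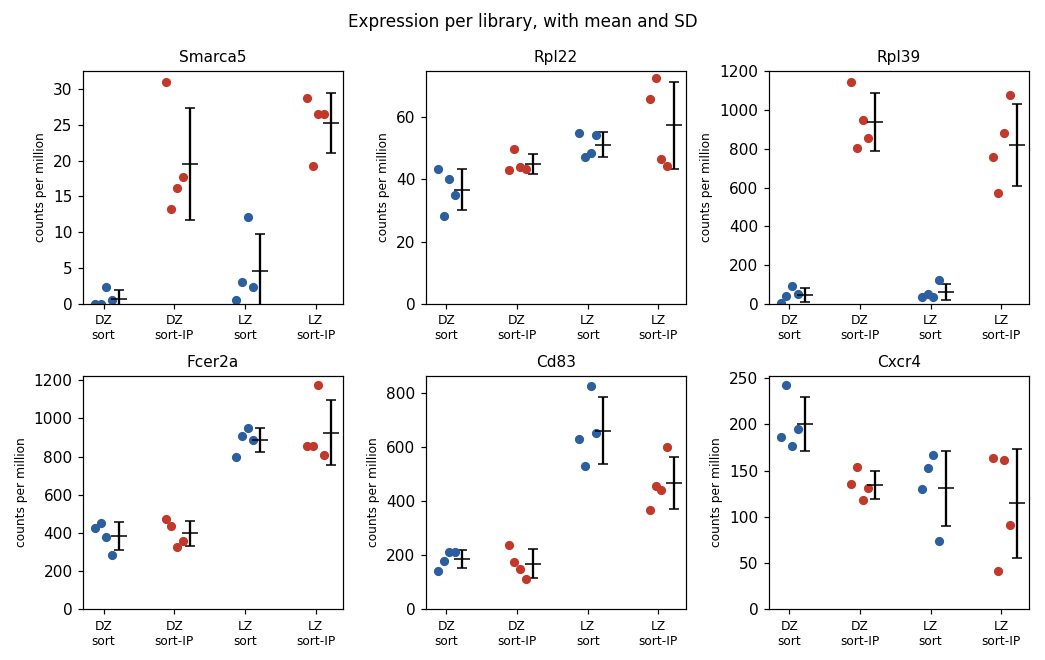
Level of Smarca5, Rpl22, Rpl39, Fcer2a, Cd83 and Cxcr4 in each of the 16 libraries, in CPM, with the mean and SD of each group of 4. Smarca5 lies at 0 to 2.36 CPM in the DZ sort libraries and at 13.2 to 30.9 in the DZ IP libraries.

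In the dark zone, 353 transcripts were higher and 260 lower in the IP than in the sorted cells (edgeR). Rpl39, a protein of the large ribosomal subunit (chromosome X, 37082520 to 37085402), stood at 939 ± 152 CPM in the IP against 45.9 ± 35.5 in sorted cells (log2 fold change 4.30 ± 0.55, adjusted p = 0.00178). Eif3e, a subunit of initiation factor 3 (chromosome 15, 43250058 to 43282719), stood at 166 ± 42.8 against 13.6 ± 5.98 CPM (3.52 ± 0.28, 0.000298). The 10 largest rises were those of Thoc2, March1, Ranbp2, Xpo1, Pyhin1, Arf6, Pum2, Dennd1b, Plek and Phf6, from 4.35 to 5.49, among them the mRNA export and nuclear pore genes Thoc2 and Ranbp2 and the exportin Xpo1. Thoc2 (chromosome X, 41794991 to 41920674) had 98 counts in the IP and 2 in the sorted cells, a ratio of 51.2 with a 95% counting interval of 13.8 to 429, and March1 had 115 and 3, a ratio of 40.1 (13.4 to 197). Falls were smaller. The 10 largest were those of Rpph1, Toporsos, TMSB4X, Clec2i, Bola3, Ifnar1, Lrrc73, Slc27a3, Tmsb4x and Tbx6, from −2.42 to −1.44. Rpph1, the RNA of ribonuclease P, stood at 3.82 ± 2.72 against 23.0 ± 15.5 CPM, and Tmsb4x, which encodes an actin-binding peptide, at 1864 ± 283 against 5094 ± 1866 CPM (adjusted p = 0.0143).

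With edgeR's quasi-likelihood test, 353 genes were higher and 260 lower in DZ IP than in DZ sort, of 7757 tested. The count was 202 within the libraries with Xist counts and 1936 within those without, and all 613 genes kept their direction with Xist and the 607 that could be fitted kept it without. Leaving out 1 library gave 984 genes without DZ sort replicate 4 and 222, 242, 254, 316 and 317 without DZ IP replicates 3, 1, 2, 4 and DZ sort replicate 1. Of 55 named genes past the threshold, 32 passed without each of the 8 libraries. Among the largest falls the call was lost for Rpph1 and Clec2i without any of 6 libraries (adjusted p up to 0.0982 and 0.106), Toporsos and Lrrc73 without any of 4 (0.0763 and 0.0635), Slc27a3 without any of 3 (0.0678) and Ifnar1 without DZ IP replicate 3 (0.0593).

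Translation factor genes passed as a list in DZ IP, higher in the IP, with 3 of 23 past the threshold over all genes, 8 adjusted over the list alone, and a median log2 fold change of 0.38 (camera adjusted p = 1.87e-05). With an estimated correlation the adjusted p was 0.572. Its members past the threshold were Eif3e, Eif4b (0.77 ± 0.14) and Nap1l1 (0.79 ± 0.15), while Gnb2l1 (0.19), Eef2 (0.44) and Fau (0.87) were not past it. Of 78 ribosomal protein genes 6 rose and 2 fell, with the same counts adjusted over the list alone (median 0.23, adjusted p = 0.000477, and adjusted p = 0.844 with an estimated correlation). Rpl22l1, a paralog of Rpl22 (chromosome 3, 28805436 to 28807424), stood at 255 ± 64.8 against 13.6 ± 8.20 CPM (4.15 ± 0.38), Rpl7 at 1476 ± 162 against 643 ± 102 and Rpl19 at 1094 ± 90.8 against 405 ± 174. Rps19 (0.13), Rplp1 (−0.37) and Rpsa (0.27) were not past the threshold. The ribosomal protein median was 0.89 within the libraries with Xist counts and −0.21 within those without, so its direction does not hold within both, whereas that of the translation factors was 0.58 and 0.32. Of 12 histone genes 0 passed over all genes (edgeR) and 3 adjusted over the list alone, with a median of 1.13 (adjusted p = 0.0135, and 0.844 with an estimated correlation), 3.14 with and −0.02 without Xist counts. Hist1h1e, a linker histone gene, stood at 132 ± 82.7 against 28.8 ± 32.8 CPM (adjusted p = 0.0690).

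Other groups in DZ IP had members past the threshold without a call for the list. Of 24 germinal centre identity genes 4 rose and 1 fell, 6 and 2 adjusted over the list alone (camera adjusted p = 0.145). Rgs13, a regulator of G protein signalling (chromosome 1, 144138654 to 144177372), stood at 11.3 ± 3.31 against 0.968 ± 0.650 CPM, the B cell factor Pax5 at 28.1 ± 4.09 against 8.33 ± 5.17, and the germinal centre receptor gene S1pr2 at 450 ± 43.9 against 666 ± 48.2. Of 11 dark zone genes 2 rose and 1 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.780), where the median was −0.16 but the test pointed up. The fall was in the chemokine receptor Cxcr4 (134 ± 14.9 against 200 ± 29.2 CPM, adjusted p = 0.0375). Leaving out any of 6 single libraries ended the call of Cxcr4 (adjusted p up to 0.111, without DZ IP replicate 3) and any of 7 that of S1pr2 (up to 0.0947, without DZ IP replicate 2). Of 21 remodeler genes Smarca5 and Hells rose, with the same count adjusted over the list alone (camera adjusted p = 0.0537). Hells stood at 15.4 ± 6.13 against 1.31 ± 1.24 CPM, while Chd4 (0.54) and Smarca4 (−0.33) were not past the threshold. Of 70 respiratory chain genes 4 rose and 1 fell, 7 and 2 adjusted over the list alone (camera adjusted p = 0.747), with a median of −0.04, 0.25 with and −0.28 without Xist counts, where the test pointed up. Uqcrb of complex III (chromosome 13, 66900617 to 66905378) stood at 114 ± 41.2 against 6.80 ± 4.89 CPM. Atp5j lost its call without any of 6 libraries (adjusted p up to 0.110, without DZ IP replicate 1), while Cox8a passed without each library. Foxo1 (−0.25), Cd83 (−0.15), Cd86 (−0.16), Myc (0.45), Bcl6 (0.71), Ccnb1 (−0.04) and Irf4 (−0.14) did not pass, with adjusted p-values from 0.0789 to 0.955. The direction of Cd86 turned, from −0.90 with Xist counts (adjusted p = 0.16) to 1.05 without (0.0352). Among markers of other cell types, the T cell gene Lat gave −0.65 in DZ IP (adjusted p = 0.154), −0.17 with and −0.99 without Xist counts (0.777 and 0.00976), and the erythroid gene Hemgn 0.57 (0.183), 0.09 with and 1.25 without (0.846 and 0.00369). The stromal markers Pecam1 (−0.43, 0.144) and Mfge8 (−0.27, 0.672) had a median of −0.35, −0.21 with and −0.46 without Xist counts, where Pecam1 passed (0.0386).

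In the light zone Rpl39, Eif3e, Rpl22l1 and Uqcrb were again higher in the IP. Rpl39 stood at 821 ± 213 CPM in the IP against 61.6 ± 42.5 in sorted cells (log2 fold change 3.72 ± 0.40, edgeR adjusted p = 0.000753), Eif3e at 162 ± 30.9 against 15.9 ± 7.28 (3.33 ± 0.29), Rpl22l1 at 206 ± 73.2 against 24.9 ± 6.80 (3.05 ± 0.29) and Uqcrb at 78.0 ± 36.2 against 8.36 ± 4.09 (3.18 ± 0.40). The 10 largest rises were those of Nipa2, Atrx, Otud4, Pyhin1, Rnf2, Dennd1b, Gmfb, Phf6, Trim59 and Rgs13, from 3.99 to 4.67. They include the chromatin genes Atrx (25.7 ± 15.0 against 1.07 ± 0.206 CPM) and Rnf2 (10.3 ± 3.17 against 0.410 ± 0.615). The 10 largest falls were those of Dnase1l2, Rdh5, Synj2bp, Fam189b, Toporsos, Ubl4a, Smpd4, Rfk, E2f7 and Rbms2, from −1.79 to −1.38. Dnase1l2 stood at 4.15 ± 1.33 against 14.9 ± 1.28 CPM and E2f7, a cell cycle repressor, at 11.9 ± 2.20 against 31.2 ± 7.42.

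With edgeR, 283 genes were higher and 220 lower in LZ IP than in LZ sort, of 7619 tested. The count was 1998 within the libraries without Xist counts, with all 501 of the called genes that could be fitted in the pooled direction. Within those with Xist counts edgeR called 0 genes, with 1077 at an unadjusted p under 0.05, and all 503 kept their direction. Rpl39 then gave 3.06 with Xist counts (adjusted p = 0.170) and 4.49 without (1.58e-20). Leaving out 1 library gave 161, 197 and 294 genes without LZ IP replicates 4, 3 and 1, and 235 and 334 without LZ sort replicates 2 and 1. Of 48 named genes past the threshold, 27 passed without each library. Among the largest falls the call was lost for Toporsos without any of 6 libraries (adjusted p up to 0.105), Rdh5, Synj2bp and Rbms2 without any of 5 (0.0898, 0.0887 and 0.0629), and Smpd4 and Rfk without any of 2 (0.0577 each, without LZ IP replicate 4).

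Of 77 ribosomal protein genes in LZ IP 7 rose and 0 fell (edgeR), 9 and 0 adjusted over the list alone (median 0.30, camera adjusted p = 4.03e-07, and adjusted p = 0.854 with an estimated correlation). Their median was 0.91 within the libraries with Xist counts and −0.14 within those without, so this direction does not hold within both either. Of 23 translation factor genes 4 rose, 7 adjusted over the list alone (median 0.41, 0.58 with and 0.26 without Xist counts, adjusted p = 1.95e-05, and 0.659 with an estimated correlation), Eif3e and Eef1d (0.66 ± 0.12) among them. Of 70 respiratory chain genes 7 rose, 10 adjusted over the list alone (median 0.12, adjusted p = 0.0149, and 0.854 with an estimated correlation), with medians of 0.42 with and −0.05 without Xist counts. Besides Uqcrb these include Uqcrc1 (381 ± 29.4 against 203 ± 32.8 CPM), while Cox4i1 (0.14) and Atp5b (0.18) were not past the threshold. Atp5j and Cox8a lost their calls without any of 3 and 2 libraries (adjusted p up to 0.103 and 0.0690). Of 24 germinal centre identity genes 2 rose, 8 rose and 2 fell adjusted over the list alone (median 0.17, 0.13 with and 0.33 without Xist counts, adjusted p = 0.0340, and 0.659 with an estimated correlation). They were Rgs13 and Cd79a, the immunoglobulin-alpha chain of the B cell receptor (357 ± 81.9 against 164 ± 31 CPM). Of 14 histone genes 0 passed over all genes (edgeR), and 4 rose and 1 fell adjusted over the list alone (median 1.20, 2.56 with and 0.05 without Xist counts, adjusted p = 0.0340, and 0.854 with an estimated correlation). Of 21 remodeler genes Smarca5 and Hells (20.4 ± 4.91 against 2.26 ± 2.39 CPM) rose, with the same count adjusted over the list alone (camera adjusted p = 0.203). Cxcr4 (−0.16), Foxo1 (−0.21), Cd83 (−0.50), Cd86 (−0.35), Myc (0.45), Bcl6 (0.71), Ccnb1 (−0.04) and Irf4 (−0.02) did not pass, with adjusted p-values from 0.121 to 0.963. Cd86 turned here too, from −1.05 with Xist counts (adjusted p = 0.437) to 0.90 without (0.000805). Among markers of other cell types, Lat gave −0.41 in LZ IP (adjusted p = 0.261), −0.23 with and −0.56 without Xist counts, and Hemgn 0.16 (0.815), −0.53 with and 1.16 without (0.50 and 0.00109), so its direction does not hold within both. The stromal markers Pecam1 (−0.53, 0.0334, lost without any of 7 libraries) and Mfge8 (−0.49, 0.367) had a median of −0.51, −0.42 with and −0.58 without Xist counts.

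The IP effects of the 2 zones went together across genes. Over 7450 genes tested in both, the log2 fold changes correlated at a Pearson r of 0.84 and a Spearman rho of 0.78, where genes are not independent replicates. Pearson's r was 0.69 within the libraries with Xist counts and 0.88 within those without. The genes higher in the IP of both zones numbered 143, against 12 for independent lists of these sizes, those lower in both 95, against 7.38, and 0 went opposite ways past the threshold. The zones share no library, but same-numbered sorted libraries deviated together, so both effects share part of their errors and values for independent lists are too low a standard. In 18 regroupings with 2 sorted and 2 IP libraries on each side, by the same numbers in both zones, Pearson's r ranged from −0.219 to 0.579 (median 0.194) and the covariance from −0.0178 to 0.0735, against a covariance of 0.302 in the real groups. Same-numbered IP libraries carry opposite Xist status in the 2 zones, so these regroupings do not match the IP libraries by it, and none that does was run. With sorted libraries of 2 numbers in the DZ and of the other 2 in the LZ, r was 0.509 to 0.741 over the 6 choices. Then 50 to 217 genes were higher in both (2.78 to 43.8 for independent lists) and 6 to 72 lower in both (0.104 to 17.5). In the 2 choices that set Xist status against zone, 18 and 12 genes went opposite ways past the threshold, and in the other 4 it was 0. The interaction test called 0 genes of 8217 (edgeR), with 165 at an unadjusted p under 0.05, and DESeq2 also called 0. The 165 are fewer than the share of 0.05 that chance alone would give, so they are no hint of a difference. As the test recovered only 24% of simulated 2-fold changes, the 0 does not show that the IP effect is the same in both zones. For Smarca5 the difference between the IP effects was 1.67 ± 0.95 on the log2 scale (adjusted p = 1). The other marker genes gave from −0.40 (Cxcr4) to 0.35 (Cd83). Among the lists only the respiratory chain genes passed the interaction test, with a median of −0.20 over 70 genes, 0 of them past the threshold over all genes or adjusted over the list alone (camera adjusted p = 0.00554, and 0.826 with an estimated correlation).

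**Figure D2:**
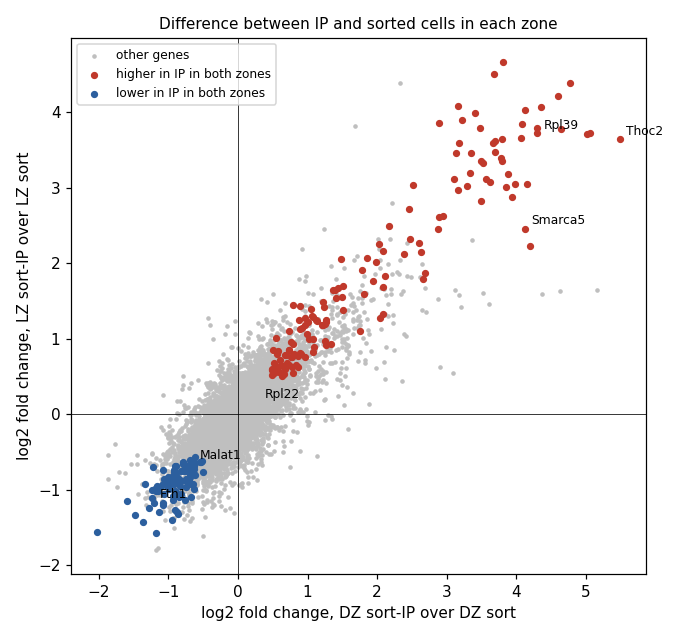
Log2 fold change of IP over sorted cells in the dark zone (x axis) and the light zone (y axis) for each gene tested in both, with genes past the threshold and higher in both zones in red and lower in both in blue. The 143 red genes reach further from 0 than the 95 blue ones.

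No difference between groups in the share of counts on ribosomal protein genes passed the exact permutation test. For IP against sorted cells this test pools opposite differences. The sorted libraries without Xist counts lay above all IP libraries in this share, and those with Xist counts lay below them. The pooled result thus does not show that the shares were alike. The share was 21.4 ± 0.950% in DZ IP against 19.9 ± 6.86% in DZ sort (n = 4 each, exact two-sided p = 0.714) and 21.7 ± 1.60% in LZ IP against 20.1 ± 5.87% in LZ sort (exact p = 0.714). Between the zones the exact p was 0.971 in the sorted cells and 0.657 in the IP. The nuclear noncoding RNAs took 0.00731 ± 0.00199% in DZ IP and 0.00911 ± 0.00406% in DZ sort (exact p = 0.429), and 0.00779 ± 0.00175% in LZ IP and 0.0116 ± 0.00549% in LZ sort (exact p = 0.286). Between the zones the exact p for these RNAs was 0.457 and 0.600. After BH adjustment within each comparison the smallest of these 8 values was 0.571.

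**Figure D3:**
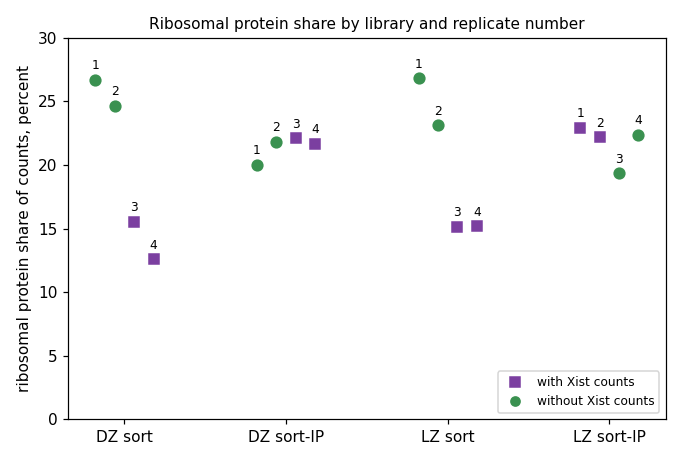
Share of each library's counts on ribosomal protein genes, in percent, by group and replicate number, with squares for libraries with Xist counts and circles for those without. In the sorted cells squares lie at 12.6 to 15.5% and circles at 23.1 to 26.8%, while IP libraries of both kinds lie at 19.3 to 22.9%.

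Between the zones, 15 of 30 light zone genes were lower and 1 higher in DZ sort (camera adjusted p = 1.60e-29, and adjusted p = 0.000237 with an estimated correlation). Of 36 mitosis genes 5 were higher, and that list did not keep its call with an estimated correlation (camera adjusted p = 1.70e-06, and adjusted p = 0.0629 with it). The chemokine receptor Ccr6 (chromosome 17, 8236043 to 8257141) stood at 14 ± 3.43 CPM in DZ sort against 135 ± 37.7 in LZ sort (log2 fold change −3.28 ± 0.25, edgeR adjusted p = 0.00062), and the activation marker Cd83 (chromosome 13, 43784775 to 43803132) at 185 ± 32.8 against 659 ± 123 (−1.84 ± 0.19, 0.00238). Rgcc, a regulator of the cell cycle (chromosome 14, 79288756 to 79301645), was higher in the DZ at 99 ± 16.1 against 16.3 ± 2.75 CPM (2.60 ± 0.18, 0.000495). Dnase1, Sepp1, Mcoln2, Lrrc73, Pafah1b3, Serinc5, Pde2a, Myl4 and Ackr4 make up the rest of the 10 largest rises, from 1.72 to 2.43. The other 9 of the largest falls were those of Ccnd2, Socs3, Egr2, Bhlhe40, Serpinb1a, Ephx1, Egr3, Hhex and Ffar2, from −3.45 to −2.15. Ccnd2, the cyclin D2 gene, stood at 1.11 ± 0.574 against 11.7 ± 2.92 CPM, and Egr2 and Egr3, transcription factors induced by antigen receptor signals, at 2.64 ± 1.82 against 16.1 ± 4.63 and 3.90 ± 1.24 against 18.1 ± 3.44. The remodeler gene Smarca4 (chromosome 9, 21616169 to 21704230) was higher in the DZ at 685 ± 99.1 against 346 ± 16.2 CPM (0.98 ± 0.14, 0.00832).

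With edgeR, 95 genes were higher and 102 lower in DZ sort than in LZ sort, of 7634 tested. With the replicate number as a block, which takes these samples as paired, 364 were higher and 406 lower. A block on Xist status alone gave 266 higher and 317 lower. Within the libraries with Xist counts edgeR called 0 genes, with 737 at an unadjusted p under 0.05, and within those without it called 312. All 197 genes kept their direction in both. Ccr6 gave −3.47 with Xist counts (adjusted p = 0.101) and −3.02 without (0.000102), Cd83 −1.80 (0.142) and −1.87 (9.51e-05), and Rgcc 2.62 (0.101) and 2.58 (5.73e-05). Leaving out 1 library gave 101, 88, 100 and 120 genes without DZ sort replicates 1 to 4 and 85, 100, 113 and 77 without LZ sort replicates 1 to 4. Of 37 named genes past the threshold, 20 passed without each library. Among the largest changes the call was lost for Sepp1 without any of 7 libraries (adjusted p up to 0.106), Mcoln2, Socs3, Ephx1 and Hhex without any of 5 (up to 0.0678, 0.0702, 0.0580 and 0.0828), Bhlhe40 without any of 4 (0.0612) and Ffar2 without any of 2 (0.0560).

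Of 30 light zone genes 15 were lower and 1 higher in DZ sort, 21 and 1 adjusted over the list alone (median −0.92, camera adjusted p = 1.60e-29, and adjusted p = 0.000237 with an estimated correlation). Ccr6, Cd83, Ccnd2 and Cd40, the receptor for T cell help (134 ± 14.5 against 249 ± 8.24 CPM), had the smallest p-values, while Dusp2 (−0.59), Il21r (−0.22) and Traf1 (0.21) were not past the threshold. With the replicate block Dusp2 was (adjusted p = 0.00411). Of 10 dark zone genes 3 were higher, 5 adjusted over the list alone (median 0.42, adjusted p = 1.65e-06, and 0.0223 with an estimated correlation). These were Pafah1b3 (500 ± 94.2 against 135 ± 31.6 CPM), Gcsam (96.9 ± 24.2 against 31.5 ± 8.78) and Tcf3 (359 ± 7.25 against 228 ± 22.9). Leaving out any of 5 libraries ended the call of Tcf3 (adjusted p up to 0.0629, without LZ sort replicate 4). Cxcr4, a chemokine receptor of dark zone cells, stood at 200 ± 29.2 against 131 ± 41.1 CPM (0.61 ± 0.23, adjusted p = 0.256, and 0.65 with adjusted p = 0.0402 with the replicate block). Foxo1 gave 0.38 (0.354, and 0.0542 with the block). Of 36 mitosis genes 5 were higher, 8 adjusted over the list alone (median 0.33, adjusted p = 1.70e-06, and 0.0629 with an estimated correlation), led by the cyclin gene Ccnb2 (267 ± 14.4 against 121 ± 14.2 CPM) and the anaphase activator Cdc20 (209 ± 43.1 against 102 ± 16.3). Leaving out any of 4 libraries ended the call of Cdc20 (adjusted p up to 0.0661, without LZ sort replicate 1). Leaving out any of 7 ended those of Cdca8 and Cenpa (up to 0.0974 and 0.0892), while Ccnb2 passed without each library. Medians of these 3 lists kept their sign within the libraries with and without Xist counts, at −0.92 and −0.97 for the light zone list, 0.20 and 0.53 for the dark zone list and 0.44 and 0.29 for the mitosis list. With the replicate block 23 light zone genes were lower and 13 mitosis genes higher.

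Of 12 resting B cell genes 2 were lower in DZ sort, 7 lower and 1 higher adjusted over the list alone (median −0.73, −0.77 with and −0.67 without Xist counts, adjusted p = 7.47e-05, and 0.0629 with an estimated correlation). The low-affinity IgE receptor Fcer2a (chromosome 8, 3681737 to 3694175) stood at 385 ± 74.3 against 886 ± 64.3 CPM (adjusted p = 0.00637) and Cd38 at 11.8 ± 4.44 against 30.8 ± 4.61, while the proton channel Hvcn1 stood at 1743 ± 110 against 2368 ± 43.3 (adjusted p = 0.153, and 0.0159 with the block). Cd38 lost its call without any of 7 libraries (adjusted p up to 0.0833, without DZ sort replicate 3). With the block 6 resting B cell genes were lower and 1 higher. Of 13 immediate early genes 3 were lower, 5 with the block, 5 adjusted over the list alone (median −0.27, −0.17 with and −0.29 without Xist counts, adjusted p = 7.47e-05, and 0.0269 with an estimated correlation), which were Egr1 (27.0 ± 5.05 against 60.4 ± 5.97 CPM), Nr4a1 and Socs3. Nr4a1 lost its call without any of 2 libraries (adjusted p up to 0.0518, without LZ sort replicate 4). Of 70 respiratory chain genes 0 passed with edgeR, over all genes or adjusted over the list alone, but 16 were higher and 0 lower with the replicate block, 30 and 0 adjusted over the list alone, and 66 had a log2 fold change above 0 (median 0.29, 0.22 with and 0.35 without Xist counts, adjusted p = 1.53e-05, and 0.652 with an estimated correlation). Myc was lower in the DZ (15.3 ± 2.58 against 32.2 ± 3.16 CPM, adjusted p = 0.0181) and lost the call without any of 5 libraries (up to 0.0621, without LZ sort replicate 4). Cd86 gave −1.36 (0.368, and 0.000606 with the block), Ccnb1 0.86 (0.385, and 0.0223 with the block), Irf4 −1.04 (0.0642, and 0.00349 with the block), and Bcl6 0.37 (0.700).

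**Figure D4:**
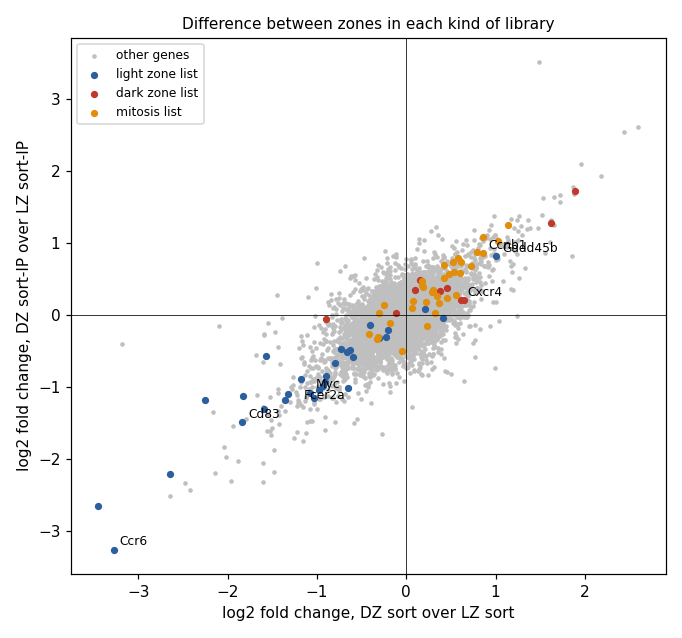
Log2 fold change of dark over light zone in the sorted cells (x axis) and in the IP (y axis) for each gene tested in both, with the light zone list in blue, the dark zone list in red and the mitosis list in orange. The light zone list has medians of −0.92 and −0.91, and the mitosis list medians of 0.33 and 0.39.

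In the IP RNA, Ccr6 and Cd83 were again lower and Rgcc higher in the DZ. Ccr6 stood at 23.0 ± 10.2 CPM in DZ IP against 214 ± 80.1 in LZ IP (−3.26 ± 0.30, edgeR adjusted p = 9.14e-05), Cd83 at 167 ± 53.8 against 466 ± 97.2 (−1.49 ± 0.20, 0.00114) and Rgcc at 104 ± 9.43 against 16.4 ± 6.07 (2.61 ± 0.21, 4.65e-05). The largest rise was that of Guca1b, a guanylate cyclase activator, at 9.66 ± 1.84 against 0.930 ± 0.888 CPM (3.51 ± 0.53). Dnase1, Ptgr1, Sepp1, Pde2a, Pafah1b3, Serinc5, Myl4 and Otub2 were next to Rgcc in the 10 largest rises, from 1.65 to 2.54. Ccnd2, Bhlhe40, Ephx1, Serpinb1a, Plbd1, Fcgrt, Egr2, Ffar2 and Slc17a9 followed Ccr6 in the 10 largest falls, from −2.65 to −2.18. Smarca4 was again higher in the DZ, at 544 ± 62.5 against 286 ± 18.7 CPM (0.92 ± 0.13, 0.00112).

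With edgeR, 106 genes were higher and 160 lower in DZ IP than in LZ IP, of 7350 tested. The count was 42 within the libraries with Xist counts and 38 within those without, and all 266 kept their direction with Xist and the 264 that could be fitted kept it without. Ccr6 gave −3.29 (adjusted p = 0.00161) and −3.22 (0.00127) in these and Cd83 −1.66 (0.00531) and −1.34 (0.0149). Leaving out 1 library gave 151, 150 and 168 genes without DZ IP replicates 2, 3 and 4 and 166 without LZ IP replicate 3. Of 50 named genes past the threshold, 34 passed without each library. Among the largest changes the call was lost for Slc17a9 without any of 3 libraries (adjusted p up to 0.0824) and for Bhlhe40 without DZ IP replicate 2 (0.0586). Over 7062 genes the zone effects in sorted cells and IP correlated at a Pearson r of 0.69 and a Spearman rho of 0.56, and at a Pearson r of 0.55 with and 0.58 without Xist counts. The genes higher in the DZ in both numbered 60 (1.31 for independent lists), those lower in both 67 (2.24), and 0 went opposite ways past the threshold. No regrouping was run for the zone effects, so independent lists, which may be too low a standard, are the only one given.

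Of 30 light zone genes 15 were lower and 1 higher in DZ IP, 20 and 1 adjusted over the list alone (median −0.91, −0.89 with and −0.83 without Xist counts, camera adjusted p = 8.05e-24, and adjusted p = 0.0242 with an estimated correlation). Besides Ccr6 and Cd83 they include the inhibitor of NF-kB Nfkbia (324 ± 30 against 639 ± 80 CPM). Of 37 mitosis genes 5 were higher, 8 adjusted over the list alone (median 0.39, 0.40 with and 0.39 without Xist counts, adjusted p = 2.10e-08, and 0.524 with an estimated correlation). These include the phosphatase gene Cdc25b (322 ± 26.5 against 152 ± 25.4 CPM), Cdc20 and Ccnb2, while Top2a (0.13) was not past the threshold. Of 11 dark zone genes 2 were higher, 3 higher and 1 lower adjusted over the list alone (median 0.34, 0.31 with and 0.32 without Xist counts, adjusted p = 5.53e-05, and 0.0752 with an estimated correlation). These were Pafah1b3 (467 ± 77.5 against 141 ± 29.7 CPM) and Gcsam (86.5 ± 16.6 against 35.6 ± 8.84). Of 9 resting B cell genes 4 were lower, 5 adjusted over the list alone (median −0.62, −0.96 with and −0.42 without Xist counts, adjusted p = 0.000417, and 0.118 with an estimated correlation). They were Fcer2a (396 ± 67.1 against 924 ± 170 CPM), Klf2, the survival gene Bcl2 and Cd38, of which Bcl2 lost its call without any of 3 libraries and Cd38 without any of 6 (adjusted p up to 0.0813 and 0.109, both without DZ IP replicate 2).

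Of 11 immediate early genes 2 were lower in DZ IP, 4 adjusted over the list alone (median −0.27, −0.39 with and −0.22 without Xist counts, camera adjusted p = 0.00527, and adjusted p = 0.0752 with an estimated correlation). They were Ier2 (43.1 ± 12.4 against 85.4 ± 24.1 CPM) and Nr4a1, which lost their calls without any of 5 and 6 libraries (adjusted p up to 0.0920 and 0.0870). Of 30 MYC and anabolic genes 1 was lower, 2 adjusted over the list alone (median −0.23, −0.22 with and −0.24 without Xist counts, adjusted p = 0.00681, and 0.0752 with an estimated correlation). It was Hspe1, a mitochondrial chaperonin gene, which lost its call without any of 5 libraries (up to 0.0930, without DZ IP replicate 2). Of 70 respiratory chain genes 0 passed with edgeR over all genes or adjusted over the list alone, and 48 had a log2 fold change above 0 (median 0.12, 0.07 with and 0.19 without Xist counts, adjusted p = 0.00554, and 0.557 with an estimated correlation). Of 13 antibody-secreting cell genes 3 were higher and 1 lower, 4 and 3 adjusted over the list alone (camera adjusted p = 0.467). The joining chain gene Jchain (376 ± 102 against 189 ± 53.5 CPM), Eaf2 and Mzb1 were higher and Irf4 lower (26.3 ± 2.97 against 58.5 ± 15.2 CPM). Jchain lost its call without LZ IP replicate 3 (adjusted p = 0.0567) and Mzb1 without any of 7 libraries (up to 0.141, without DZ IP replicate 2). Cd86 (−1.18, 0.00617), Myc (−1.08, 0.0134) and Ccnb1 (0.86, 0.0360) passed, Myc not without DZ IP replicate 3 or LZ IP replicate 3 (up to 0.0577) and Ccnb1 not without any of 5 libraries (up to 0.119, without DZ IP replicate 3). Cxcr4 (0.20), Foxo1 (0.34) and Bcl6 (0.37) did not pass, with adjusted p-values from 0.263 to 0.792.

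In the authors' deposited table for the DZ, 593 genes were higher and 332 lower in the IP at their adjusted p under 0.05, and in the authors' deposited table for the LZ 501 and 266. Of the genes in the authors' deposited table past that threshold, 602 in the DZ and 489 in the LZ were also called by edgeR in the same direction and 0 in the opposite one.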

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

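The tests of RNA held by the beads and of resting B cells carried over were chosen only after the result was seen, as were the Xist, thinning and GC settings. The others were fixed earlier, but the reading of the interaction's splits was set after its count was seen. For the GC and thinning tests a bound on the interval of the median was added after the medians were seen. Of 52 sets of 4 libraries, 4 had a sample far from the others, and chance gives about 1 in 20. Rpl22 stood at 49.7 CPM in DZ IP replicate 2 (others 42.9 to 43.9), and Irf4 at 21.9 CPM in the same library (others 27.2 to 28.1). Bcl6 stood at 715 CPM in DZ IP replicate 1 (others 468 to 505). Irf4 stood at 87.1 CPM in LZ sort replicate 4 (others 47.2 to 50.9).

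The 143 transcripts higher in the IP of both zones, among them Rpl39, Eif3e and Uqcrb, had median log2 fold changes of 1.48 in the DZ and 1.54 in the LZ. A GC content trend shared by all genes of a library is argued against as the whole cause. The lower of both medians was still 1.39 after a correction for it, with 132 and 136 of the genes past the threshold. The 11 and 7 others had median log2 fold changes of 1.27 and 0.92 before it and 0.55 and 0.62 after. Yet the 143 genes have a lower median GC content than all tested genes (41.5% against 47.4%). The correction takes out only the mean trend of each library. It cannot decide on a bias that acts on some transcripts of low GC content, which stays open. Thinning to the smallest library leaves expected fold changes as they are, so it cannot decide whether depth is the cause. It took the medians of the 133 and 126 genes still tested from 1.33 to 1.37 in the DZ and from 1.29 to 1.32 in the LZ. Of the 143, 37 and 52 lost the call, 10 and 17 of them with too few counts left to test. The others were at median log2 fold changes of 0.83 and 0.93 before and 0.79 and 0.82 after, with standard errors of 0.212 and 0.207 before and 0.242 and 0.238 after. Mean total counts were 2171110 ± 619279 in DZ IP, 2140110 ± 915958 in DZ sort, 1362810 ± 322090 in LZ IP and 2177760 ± 279712 in LZ sort. Greater depth of the IP libraries is thus argued against in the LZ, where they were shallower, and the DZ means were alike. RNA held by the beads without ribosomes stays open, since the 4 nuclear noncoding RNAs measured had a median of −0.39 in the zone where it was lower, and no IP from untagged cells was analysed here. Binding to ribosomes, which the IP groups were made to measure, stays open with it as an untested biological explanation, and the 2 cannot be told apart in these libraries. Nothing here shows that they are the only ones, and other differences in how IP and sorted RNA were prepared were not tested.

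The libraries with and without Xist counts stand apart within the groups, which is a pattern of the samples. With group and Xist status as terms, 1785 autosomal genes passed for Xist status in the 8 sorted libraries and 283 in the 8 IP libraries. The fit took the 8 sorted libraries as independent, although same-numbered DZ and LZ libraries deviated together, so the first count may be too high. A batch that follows sex would raise it as sex would, so it does not decide whether sex of the animals alone is the cause. Of 78 ribosomal protein genes, 59 were lower with Xist counts in the sorted cells (median −0.999) and 3 of 76 in the IP (median 0.10). A handling batch shared by the same libraries may add to this. The labels give no batch, and a batch that follows sex cannot be told apart from it here.

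Of resting B cell genes 2 of 12 in sorted cells and 4 of 9 in the IP were higher in the light zone, Fcer2a and Cd38 in both, but the list lost its call with an estimated correlation (adjusted p = 0.0629 and 0.118) and Cd38 without any of 7 and 6 single libraries. Resting cells carried over in the light zone gate may account for it, and the test of this was set after the values were seen. Members lower in the DZ were 10 of 12 in sorted cells (83.3%, exact 95% interval 51.6 to 97.9%) and 6 of 9 in the IP (66.7%, 29.9 to 92.5%). The most abundant member, Hvcn1, stood at 1743 ± 110 CPM in DZ sort and 2368 ± 43.3 in LZ sort, and Klf2 and Bcl2 are also in other lists. So few genes do not decide it, the gates of the sort, which would remove resting cells, are not given in the sources used here, and a zone difference in these genes within germinal centre cells stays open as well.

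Other splits of the same libraries were counted for each comparison. Of 35 splits of 4 against 4, only the real one gave as many genes in DZ IP against sort (613, highest other 8), LZ IP against sort (503, highest other 14) and DZ against LZ IP (266, highest other 102). That is 1 of 35 each, the smallest value that 35 splits can give, not adjusted over the comparisons. Chance is thus unlikely there but not excluded. For DZ against LZ sort 2 of 35 gave as many, the real one with 197 genes and the split by Xist counts with 1326, which points to a structure of the samples, so chance cannot be excluded by this count. Of the 8 splits that part all 4 pairs of numbers, only the real one gave as many, the highest other giving 0. As 1 of 8 is the smallest value these can give, they do not exclude chance either. Only the real split was fitted with the replicate block, where it gave 770. The interaction gave 0 genes, which each of the 100 splits drawn reaches whatever it holds (highest other 217), so this count says nothing about chance there.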

How the results depend on the processing

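Fits with or within Xist counts, thinning, GC correction, summed letter-case symbols and sorted libraries of different numbers in each zone were tests chosen after the data were seen; the others were planned. Over 547 named gene and comparison pairs, 10364 values kept their side of the threshold, 628 lost the call, 134 gained it and 6 reversed with a call. Of the 10364, 9803 kept their direction and 561, in 174 pairs, changed sign with neither value past the threshold. The counts below give all genes past the threshold in DZ IP against sort (613), LZ IP against sort (503), DZ against LZ sort (197) and DZ against LZ IP (266), and the cause of each shift was not tested, except that a fold of at least 2 is a higher bar. DESeq2 called 926, 767 and 318 in the first 3, and a fold of at least 2 left 301, 197, 110 and 115. The replicate block gave 213 in LZ IP against sort, 97 in DZ against LZ IP and, in the sorted groups that the numbers were taken to pair, 770. There it changed no list call. Besides the genes given above, the named genes Cdc25b, Cdca3, Pold1, Spib, Mzb1, Eaf2, Vpreb3, Cst3, Gas5, Cox6a1, Atp5b, Hist1h1e, Ldha, Bid and Bcl11a gained a call, and it changed no other call of a named gene. In the other comparisons samples share only a number. Same-numbered libraries correlated there from −0.53 to 0.28, and not every library correlated best with its own number. In LZ IP against sort and DZ against LZ IP each number sets a library with Xist counts against one without, so those 2 blocked counts rest on mismatched libraries. All 16 libraries in one fit gave 869 in LZ IP against sort and 307 in DZ against LZ sort. An Xist block gave 942, 583 and 473 in all but LZ IP against sort. Libraries with Xist counts gave 202, 0, 0 and 42, and those without gave 1936, 1998, 312 and 38, from 4 libraries in place of 8, which cannot account for the 3 counts above those of all 8. For the 0 in LZ IP against sort and in DZ against LZ sort, edgeR had 1077 and 737 genes at an unadjusted p under 0.05. Thinning gave 359, 263 and 146 in all but DZ against LZ sort, and the GC correction with the replicate block 842 in DZ against LZ sort. Leaving out 1 library gave 222 to 984, 161 to 730, 77 to 120 and 150 to 319, and 0 for the interaction, which was 0 under each setting run. With an estimated correlation the lists past the threshold went from 3, 5, 6, 7 and 1 (interaction) to 0, 0, 3, 1 and 0. The correlation of IP effects (0.84) was 0.869 over genes of at least 50 CPM, 0.862 with the replicate block, 0.801 with DESeq2, 0.80 with no filter and 0.793 thinned, and 0.80 to 0.84 with 1 library left out. With sorted libraries of different numbers in each zone it was 0.735, 0.657, 0.741 and 0.722 where both kinds of Xist status stood in each, and 0.509 and 0.576 where they did not, each from fewer libraries. Log2 fold changes that reversed and were past the threshold were Snhg8 1.19 in DZ IP with Xist counts and, without, Mcm6 −0.46, Zfp36 0.76 and Cd86 1.05 in DZ IP and Zfp36 0.50 and Cd86 0.90 in LZ IP. Shares or library sizes without immunoglobulin or mitochondrial genes and other pseudocounts were not run, since no such rows and no normalized values entered. At 993379 counts in the smallest library, a gene at 1 CPM has about 1 count, so low genes rest on few counts.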

Other observations

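The test of detained introns below was fixed before its values were seen, and the values within the libraries with and without Xist counts were chosen only after the result was seen. In the IP against sorted cells, several groups had single members past the threshold (edgeR) without a call for the list. Of 33 DNA replication genes Hells and Pola1 were higher in both zones, 1 member adjusted over the list alone in the DZ, and 5 higher and 1 lower in the LZ (camera adjusted p = 0.747 and 0.203). Pola1, a DNA polymerase subunit, stood at 38.7 ± 3.24 against 16.5 ± 2.67 CPM in the LZ (n = 4). Its DZ call was lost without any of 7 libraries (adjusted p up to 0.118, without DZ IP replicate 1). Of 30 MYC and anabolic genes 2 were higher in the DZ and 5 in the LZ, with the same counts adjusted over the list alone (0.724 and 0.0541). The chaperonin gene Cct5 stood at 529 ± 47.9 against 320 ± 12.5 CPM in the DZ and 455 ± 35.0 against 290 ± 9.61 in the LZ. Of endoplasmic reticulum genes 2 were higher and 2 lower of 27 in the DZ and 0 and 1 of 25 in the LZ, 4 and 5 and then 1 and 3 adjusted over the list alone, with adjusted p = 0.878 and 0.912 and a median whose sign differed from the test's in both zones (0.04 and −0.06). The signal peptidase gene Spcs3 was lower in both (39.7 ± 10.5 against 103 ± 13.1 CPM in the DZ), in the LZ not without LZ IP replicates 3 or 4 (adjusted p up to 0.0509). Of 11 dark zone genes Rgs13 was higher in the LZ, with 2 higher and 1 lower adjusted over the list alone (0.592). Medians with and without Xist counts differed in sign for DNA replication genes in the DZ (0.14 and −0.15), for endoplasmic reticulum genes in both zones (0.12 and −0.14, and 0.07 and −0.19), for light zone genes in both (−0.05 and 0.32, and −0.12 and 0.28), for snoRNA hosts in the DZ (0.12 and −0.21) and for resting B cell (0.21 and −0.12) and myeloid genes (0.31 and −0.34) in the LZ. Differences in sign with a median within 0.01 of 0 are left out.

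Of 13 antibody-secreting cell genes Trp53inp1 and Tnfrsf13b were higher in DZ IP and Tnfrsf13b in LZ IP, 3 and 0 and then 1 and 1 adjusted over the list alone (camera adjusted p = 0.158 and 0.637). Tnfrsf13b lost its LZ call without LZ IP replicates 1 or 3 (adjusted p up to 0.0661). Junb was the 1 immediate early gene past the threshold in each zone (124 ± 43.1 against 49.4 ± 8.48 CPM in the DZ), with adjusted p = 0.847 and 0.912 for the list, 1 higher in the DZ and 2 higher and 1 lower in the LZ adjusted over the list alone. Its LZ call was lost without any of 5 libraries (adjusted p up to 0.0800, without LZ IP replicate 4). Light zone genes had 0 higher and 1 lower in each zone, the cytokine receptor Il10ra (0.765 and 0.912), with the same counts adjusted over the list alone. In the DZ its call was lost without any of 5 libraries (up to 0.0714, without DZ IP replicate 2). Mitosis genes had 0 past the threshold with edgeR in either zone, with adjusted p = 0.594 and 0.0868, as did resting B cell genes (0.711 and 0.905), and both had 0 adjusted over the list alone. The mitosis medians turned with Xist status, at 0.04 with and −0.35 without Xist counts in the DZ and 0.10 and −0.53 in the LZ. The snoRNA host Snhg5 was lower in both zones, 1 of 8 in each (0.878 and 0.585), 1 and 2 lower adjusted over the list alone, and lost its calls without any of 5 libraries in each (up to 0.10 and 0.0943). The nuclear noncoding RNAs had 0 of 4 over all genes with edgeR or adjusted over the list alone (0.735 and 0.592), with Malat1 at 14.2 ± 1.86 against 21.9 ± 4.61 CPM in the DZ. Casp8 was the 1 apoptosis gene past the threshold over all genes in each zone, and lower (0.724 and 0.801), while adjusted over the list alone 1 was lower in the DZ and 3 were higher and 2 lower in the LZ. It lost the call without any of 6 libraries in the DZ and 2 in the LZ (up to 0.129 and 0.0793). Short-lived regulators had Kmt2a higher and Kmt2d lower in the DZ (0.607), lost without any of 7 and 4 libraries (up to 0.108 and 0.0646), and 0 with edgeR in the LZ (0.686). Adjusted over the list alone, 1 was higher and 1 lower in the DZ and 2 higher and 1 lower in the LZ.

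Between the zones, lists without a call in sorted cells and IP were DNA replication (camera adjusted p = 0.572 and 0.922), germinal centre identity (0.124 and 0.463), ribosomal protein (0.802 and 0.478), translation factor (0.852 and 0.467), snoRNA host (0.256 and 0.184), nuclear noncoding RNA (0.75 and 0.999), histone (0.867 and 0.398), endoplasmic reticulum (0.676 and 0.0988), remodeler (0.996 and 0.994), apoptosis (0.884 and 0.190) and short-lived regulator genes (0.256 and 0.278). Over all genes, edgeR had 2 germinal centre identity genes higher in sorted cells and 3 higher and 1 lower in the IP, 1 snoRNA host lower in each, 1 remodeler higher in sorted cells and 1 higher and 1 lower in the IP, 2 apoptosis genes and 1 short-lived regulator lower in the IP, 1 translation factor and 1 histone gene higher in the IP, and 0 in the rest. Adjusted over the list alone, it had 2 germinal centre identity genes higher in sorted cells and 5 higher and 5 lower in the IP, 1 snoRNA host lower in each, 1 remodeler higher and 1 lower in sorted cells and 2 and 1 in the IP, 2 apoptosis genes higher and 1 lower in sorted cells and 2 lower in the IP, 4 short-lived regulators lower in the IP, and 1 translation factor and 1 histone gene higher in the IP, with 0 in the rest. Antibody-secreting cell genes in sorted cells had Derl3 lower over all genes, 1 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.757), and Derl3 lost its call without any of 7 libraries (up to 0.114, without LZ sort replicate 4). Median and test differed in sign for these in sorted cells (0.04, test down), for histone genes in sorted cells (−0.09, test up) and for germinal centre identity genes in the IP (−0.07, test up), as they did in the IP against sorted cells for immediate early (−0.07, up), DNA replication (−0.01, up) and snoRNA host genes (0.04, down) in the DZ and for light zone (0.02, down), resting B cell (0.0012, down) and myeloid genes (−0.07, up) in the LZ. They also did for myeloid genes in DZ against LZ IP (−0.08, up) and immediate early genes in the interaction (−0.0059, up). With the replicate block edgeR had, in sorted cells and over all genes, 3 DNA replication genes higher and 1 lower, 5 and 1 germinal centre identity genes, 3 and 2 apoptosis genes, 2 and 2 antibody-secreting cell genes, 1 and 1 histone genes, 1 and 1 remodelers, 2 ribosomal protein genes higher, 1 myeloid gene higher, and 4 MYC and anabolic genes, 4 short-lived regulators and 2 snoRNA hosts lower. The MYC and anabolic list in sorted cells had 0 past the threshold with edgeR without the block (camera adjusted p = 0.572). Between the zones, medians with and without Xist counts differed in sign in sorted cells for DNA replication (0.07 and −0.01), histone (0.11 and −0.03), MYC and anabolic (−0.14 and 0.04), ribosomal protein (−0.13 and 0.09), translation factor (−0.02 and 0.04) and T cell genes (−0.18 and 0.35), erythroid genes (−0.30 and 0.04) and stromal genes (−0.05 and 0.02). In the IP they did for DNA replication (0.07 and −0.16), germinal centre identity (0.02 and −0.05), histone (0.36 and −0.34) and myeloid genes (−0.17 and 0.03). Among the members of these lists the pro-apoptotic gene Bid was lower in DZ IP (185 ± 18.4 against 288 ± 34.5 CPM) and the germinal centre GTPase gene Nuggc higher (377 ± 60.4 against 221 ± 20.7 CPM).

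Markers of other cell types were few among the genes measured. Of myeloid markers 3 or 4 were tested, with adjusted p = 0.878, 0.674, 0.75 and 0.778 in the 4 comparisons. Adjusted over the list alone, 1 was higher and 1 lower in DZ IP against sort, 1 higher in LZ IP against sort, 0 passed (edgeR) between the sorted cells and 1 was higher in DZ against LZ IP. Cst3, a protease inhibitor gene that B cells also express, was higher in the IP of both zones (680 ± 70.1 against 425 ± 72.4 CPM in the DZ), which was lost without any of 4 libraries in the DZ and 5 in the LZ (adjusted p up to 0.0855 and 0.0726). The macrophage marker Cd68 was lower in DZ IP (11.6 ± 1.58 against 23.2 ± 6.29 CPM), which was lost without any of 5 libraries (up to 0.101, without DZ IP replicate 2). T cell, stromal and erythroid markers had under 3 members tested and so no list test. Lat stood at 41.5 ± 14.6 CPM in DZ sort and 37.4 ± 5.47 in LZ sort, Pecam1 at 103 ± 9.97 and 147 ± 11.9, Mfge8 at 13.7 ± 5.65 and 9.35 ± 2.09, and Hemgn at 32.6 ± 12.1 and 37.6 ± 20.8. Between the sorted cells Pecam1 gave −0.52 (adjusted p = 0.0537, and 0.0107 with the replicate block). Pecam1 fell in LZ IP against sort, to 102 ± 9.68 CPM, and lost that call without any of 7 libraries (up to 0.104, without LZ IP replicate 4). Of the natural killer markers 0 were tested in any comparison.

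It was asked as a hypothesis whether transcripts with detained introns, which tend to stay in the nucleus, hold a lower share of the IP RNA. Of 21 such genes tested from a list of 23, 2 were higher and 0 lower in DZ IP and 1 higher and 2 lower in LZ IP, with medians of 0.02 and −0.22. The larger camera p of both zones was 0.624 (LZ, with 0.583 in the DZ, where the test pointed up), so no fall of the list was seen. Counts per gene from a 3' end protocol do not tell a transcript with a detained intron from a spliced one of the same gene. The test therefore cannot decide the hypothesis.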
